A study of Mus musculus with 3 samples.

How the data were processed

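Single-cell RNA sequencing was done on viable endothelial cells sorted from mouse gastrocnemius muscle (strain C57BL/6N), gated as CD31+, CD45- and negative for SYTOX blue. The series held 3 libraries, with 1 library in each group. The sedentary group came from single-housed mice without a wheel, and the running group from single-housed mice with 14 days of voluntary wheel running. The third group was labelled as receiving no treatment, its library was titled only as muscle cells, and its housing was not given in the sources used here. No date or batch was given for any library, and most untreated capillary-like cells fell into clusters of their own. Whether that library came from a separate experiment is therefore unknown, and for it batch and group cannot be told apart, which limits each comparison and each count that uses it. How many animals went into each library was also not given.

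The deposited values were raw UMI counts per gene and cell barcode, and the values of each matrix were whole numbers. Per the labels' protocols, libraries were made with the 10x Chromium Single Cell 3' kit, version 2. Per the submitters' processing notes, the counts were made with Cell Ranger 2.0.2 on the build GRCm38.p5. The gene annotation release and the way cells were called were not given in the sources used here. Each matrix had 41605 gene rows, and rows that shared a symbol were kept apart by their Ensembl ID, the row with most UMIs taking the plain symbol. Positions of named genes were taken from GENCODE release M21, which uses GRCm38.

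The libraries held 11715 barcodes and 19611619 UMIs. Barcodes were kept with at least 300 detected genes and at most 10% mitochondrial UMIs, which left 4326 untreated, 4016 sedentary and 3212 running barcodes. Scrublet, run per library in scanpy with an expected rate of 0.05, marked 2 of 11554 barcodes (0.0173%), so it did not work as a doublet filter here. The marked barcodes were left out, and 11552 cells were kept. An alternative left out the highest 5% of doublet scores in its place.

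Counts were scaled to 10000 per cell and log-transformed. The libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. Clusters were named from 20 marker lists by the mean log2 level of each list's markers, centred over the clusters, and a name needed at least 3 detected markers. The lists were fixed before the data were examined, as were the comparisons, the 21 gene lists, the rule for named genes and most alternatives. Atf3 and Atf4 were chosen because the study was known to describe a capillary state marked by them. Results on Atf3 and Atf4 are therefore not independent of that description. The score limits for naming (at least 0.3 for a vessel class, at least -0.5 for endothelial genes as a whole and at least 1.0 for a non-endothelial type) were set after the data were seen, so shares of the unnamed clusters are given as well. The limit for endothelial genes was not applied to clusters past the limit for lymphatic genes. The lymphatic-like cluster scored -0.647 for endothelial genes and was counted as endothelial-like.

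UMIs were summed over the cells of a class in each library and scaled to CPM, the UMIs of a gene relative to those of the whole class in that library. Cells are not replicates, so no test was made between groups. Log2 ratios used a prior count of 0.5 and carry exact 95% intervals for a ratio of Poisson counts. Shares carry exact Clopper-Pearson 95% intervals, and the interval of a difference between shares combines the distances from both shares to their exact bounds as the root of the sum of squares. Intervals of list medians came from 1000 Poisson draws of the counts. All of these intervals cover counting error only, and the differences between groups have no replicate check. A share of 0 is given with the limit that 3 counts would allow. The gene lists were described by the median log2 ratio of members with at least 20 UMIs over the libraries, and by its percentile among 10000 random lists of the same size matched on mean expression. A list member was called higher or lower in the running library where it differed by at least 1.25-fold in the same direction from both other libraries. Both ratios share the running library, so the mean number of such members in the random lists is given beside each count.

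Named genes followed a rule. In capillary-like cells they needed at least 100 UMIs over the running and sedentary libraries and the same sign against both other libraries, and were ranked by the smaller of the 2 ratios. The 12 highest and 12 lowest were named, and 5 each way in artery-like and vein-like cells, and 1 gene that met this rule is not reported here. Between the untreated and sedentary libraries the 5 highest and 5 lowest ratios were named. Mitochondrial and ribosomal protein genes, models known only by a number and markers of non-endothelial types were left out of these comparisons. Atf3, Atf4, Mki67 and 2 to 4 members of each gene list with the largest ratios were always named. Between cells with and without an Atf3 UMI, the 12 largest higher and 8 largest lower genes were named among those past the threshold that went the same way in each library.

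To compare shares of cells with an Atf3 UMI, each cell was thinned at random to 1000 UMIs and shallower cells were left out. The thinned UMIs were then summed per library over capillary-like cells with and without an Atf3 UMI. These 6 sums were compared with edgeR's quasi-likelihood test, with library as a block, TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. The fit left 2 residual degrees of freedom, and Atf3 was left out of the genes tested. The libraries are different treatments, so the spread includes any difference of the contrast between them. The dispersion was estimated with information shared over all genes. The SE and p of a gene therefore rest largely on this shared value. They can understate how much its contrast differed between the libraries. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one. Alternatives changed the cell filters, clustering, scaling, thinning, block, low-count filter and tool (DESeq2), or left out each library in turn.

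Both methods were tested on simulated data. Counts were drawn for 12241 genes at the UMI totals of the running and sedentary libraries. They were Poisson draws from a shared gene profile, apart from the altered genes, with no variation between cells or libraries and genes drawn independently. Intervals held the true ratio for 96.2% of genes and for 94.5% of the 200 altered genes. Of 200 unaltered lists, 3.5% lay outside percentiles 2.5 to 97.5, and 100% of lists shifted by 0.25 lay above. These rates cover counting error only and do not show how list percentiles behave between real libraries. In simulated sums of cells with and without an Atf3 UMI over 7518 genes, the test recovered 23.4% of genes altered 1.5-fold, 50.0% of those altered 2-fold and 87.9% of those altered 4-fold. Of its 110 calls, 2 were false. The simulated libraries did not differ from each other apart from depth. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.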

Results

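The data were UMI counts of single endothelial cells sorted from mouse gastrocnemius muscle in 3 libraries, with 1 library in each of the untreated, sedentary and running groups. The untreated library had 4376 barcodes and 8002866 UMIs, with a median of 1582 UMIs per barcode. The sedentary library had 4079 barcodes and 5625068 UMIs, with a median of 1122. The running library had 3260 barcodes and 5983685 UMIs, with a median of 1518. After filtering, 4325, 4015 and 3212 cells were kept. No group had a replicate, so values are set side by side with intervals that cover counting error only.

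The first comparison asked which vessel types the sorted cells came from in each library. Most cells were in clusters named capillary-like from their marker genes, and these made up 59.4% of endothelial-like cells in the untreated, 75.6% in the sedentary and 74.99% in the running library. Artery-like cells made up 26.1%, 16.8% and 14.6%, and vein-like cells 12.4%, 6.25% and 7.75%. Over the alternatives the untreated artery-like share ranged from 14.1% at Leiden resolution 0.5 to 37.2% when clustered without stress genes, and the untreated capillary-like share from 48.5% to 72.0%. Lymphatic-like cells, led by the chemokine gene Ccl21a and the hyaluronan receptor gene Lyve1, were 27 of 4263 untreated, 10 of 3935 sedentary and 44 of 3135 running cells. As running minus sedentary, the capillary-like share differed by -0.561 percentage points (95% interval -2.61 to 1.48), the artery-like share by -2.27 (-3.99 to -0.543), the vein-like share by 1.499 (0.285 to 2.74) and the lymphatic-like share by 1.15 (0.713 to 1.64). The artery-like difference was 6.06 points when each library was clustered alone and the vein-like difference was -0.603 points with a minimum of 500 genes per cell, so neither direction was stable. The capillary-like difference was 5.33 points with that minimum and -7.93 points with each library clustered alone.

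**Figure D1:**
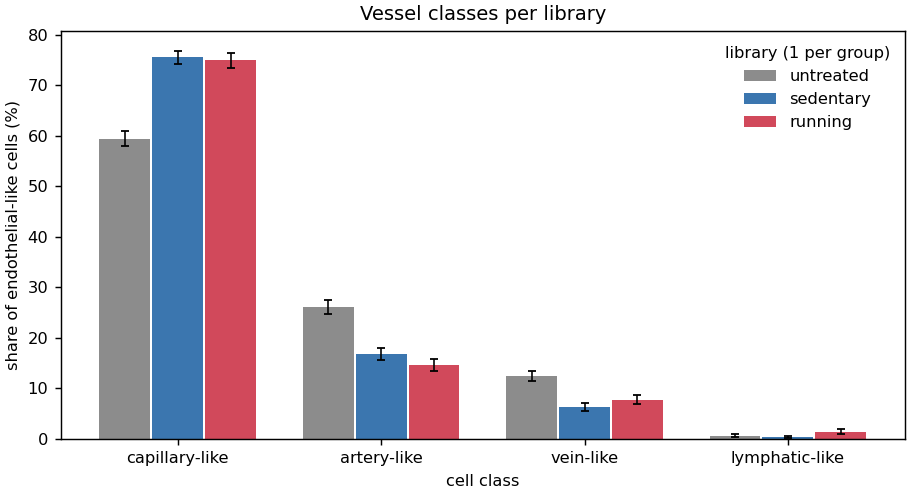
Share of endothelial-like cells (%, vertical axis) in each vessel class (horizontal axis) for the 3 libraries, with bars for the share and whiskers for the exact 95% binomial interval. Capillary-like cells were 59.4% of the untreated library and 75.6% and 74.99% of the sedentary and running libraries.

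The capillary-like class came from different clusters in different libraries. Clusters 0 and 3 held 1478 and 790 untreated cells, but 24 and 24 sedentary and 53 and 31 running cells. Clusters 2, 4 and 5 held 884, 818 and 1223 sedentary and 1192, 568 and 507 running cells, but 81, 55 and 129 untreated cells. Cluster 0 had the stress genes Rhob, Ddit4 and Jun among its leading genes, and cluster 2 had Jund, Junb, Socs3 and Cdkn1a. A cluster mostly of 1 library may be that library and not a cell type. Cluster 5 had a median of 677 UMIs per cell, against 1273 to 1580 in clusters 0, 2, 3 and 4. Within the capillary-like class the median was 1440 UMIs in the untreated, 930 in the sedentary and 1336 in the running library. Outside the named classes, an endothelial cluster led by Penk and Itm2a held 61 untreated, 43 sedentary and 40 running cells. Of kept cells, a non-endothelial cluster with Acta2, Kcnj8 and Dcn held 1.04%, 0.299% and 1.18%, and a cluster with the muscle fibre genes Acta1 and Ckm 0.393%, 1.49% and 1.03%. An erythrocyte-like cluster held 0 of 4325 untreated cells, which allows a share of up to 0.069%, and 8 sedentary and 6 running cells. The sort on CD31 and CD45 sets which cells could enter, and these shares are not shares of the muscle.

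The comparison of running with sedentary cells asked how voluntary running relates to gene expression in muscle endothelium. In capillary-like cells the running library had lower levels of Edn1, which encodes the vasoconstrictor endothelin-1, at 36.3 CPM against 80.9 (log2 ratio -1.15, 95% interval -1.46 to -0.86). Sox18, a transcription factor gene of vessel development, was lower by a similar ratio of -1.07 (-1.37 to -0.79). Timp4, which encodes an inhibitor of matrix metalloproteinases, was at 647 CPM against 1213 (-0.91, -0.98 to -0.83). Higher in the running library were Tnf, which encodes an inflammatory cytokine (1.48, 0.96 to 2.06), the signalling regulator gene Trib1 (1.30, 0.95 to 1.67) and the early response genes Egr3 (1.22, 0.73 to 1.73), Arc (0.92, 0.36 to 1.53) and Egr2 (0.92, 0.34 to 1.55). Cluster 2, with early response genes among its leading genes, held 22.0% of sedentary and 37.1% of running kept cells. Handling of the sample during dissociation was not tested for these genes and stays open. Ccl21a had the highest ratio, at 85.1 CPM against 11.6 (2.85, 2.40 to 3.38). The rule required the same sign against the untreated library, where the ratio was -2.01 for Edn1, -1.43 for Sox18, -1.09 for Timp4, 2.54 for Tnf and 4.56 for Ccl21a.

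Of 7148 genes that the rule could have named, others were also named. Lower in the running library were Il2 (-1.31), the alcohol dehydrogenase gene Adh1 (-1.03), Ncald (-1.14), Arhgap21 (-1.10), Trappc8 (-0.92), Nuak1 (-0.91), the elastin gene Eln (-0.88) and Scamp1 (-0.87). Higher were Scgb3a1 (1.22), Ppm1j (1.09), the class I antigen gene H2-Q6 (1.05), the matrix protein gene Mgp (1.01), and Id4 and Ggct (each 0.96). Id4 and Ggct had equal capillary-like counts of 46, 43 and 88 UMIs in the untreated, sedentary and running libraries, and different artery-like counts of 21, 14 and 11 against 11, 9 and 12. Ccl21a and H2-Q6 have near-identical copies among which the counting could split reads, so their levels are uncertain. Lymphatic markers together were at 54.2, 78.9 and 164 CPM in untreated, sedentary and running capillary-like cells, and without Ccl21a at 50.7, 67.3 and 78.6 CPM. Of the UMIs without Ccl21a, Flt4 gave 194 of 203, 225 of 237 and 253 of 290. That sum therefore says little about the other lymphatic genes. These had few UMIs, with Lyve1 at 1, 0 and 9, Thy1 at 1, 4 and 14 and Mmrn1 at 2, 2 and 7. Reln had 1, 2 and 5 UMIs, Prox1 3, 3 and 2 and Pdpn 1, 1 and 0. Pericyte markers were at 195, 151 and 229 CPM. Edn1 lies on chromosome 13 from 42301476 to 42307990, Timp4 on chromosome 6 from 115241892 to 115252205 and Tnf on chromosome 17 from 35199381 to 35202007 (GRCm38).

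**Figure D2:**
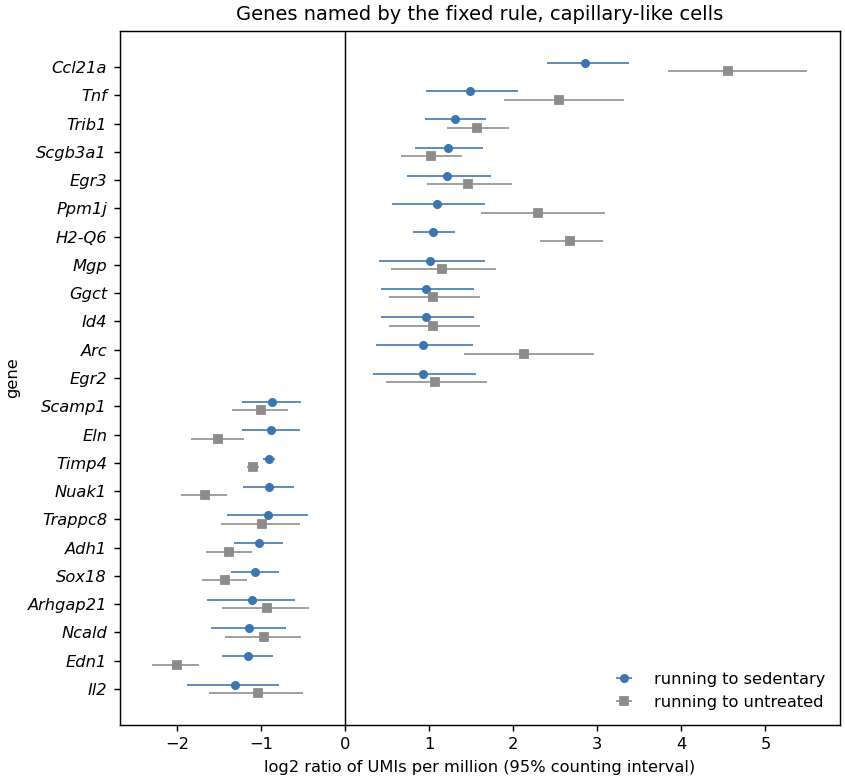
Log2 ratio of CPM in capillary-like cells (horizontal axis) for the reported genes named by the rule (vertical axis), running to sedentary (circles) and running to untreated (squares), with lines for the 95% counting interval. Ccl21a had the highest ratio, 2.85 against the sedentary library, and Il2 the lowest, -1.31.

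Atf3 is a stress-induced transcription factor gene and belongs to the immediate-early and tissue dissociation list. The level of Atf3 was 360 CPM in running, 200 CPM in sedentary and 190 CPM in untreated capillary-like cells. The log2 ratio was 0.85 (0.72 to 0.98) to the sedentary and 0.92 to the untreated library. Atf4, the transcription factor gene of the amino acid response, had a ratio of 0.27 (0.14 to 0.39). The proliferation marker Mki67 had 14 running, 3 sedentary and 6 untreated UMIs. Its log2 ratio was 1.98 (0.31 to 4.595) to the sedentary and 1.27 (-0.13 to 3.01) to the untreated library. These UMIs came from 6 of 2351 running, 2 of 2973 sedentary and 4 of 2533 untreated cells, with shares of 0.255% (0.094 to 0.555), 0.067% (0.008 to 0.243) and 0.158% (0.043 to 0.404). The intervals of these shares overlapped, and with so few cells whether the share differed cannot be told. The interval of the log2 ratio treats UMIs of the same cell as independent, so it is too narrow.

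Among the gene lists, immediate-early and tissue dissociation genes stood furthest above random lists in the running against the sedentary library, with a median log2 ratio of 0.50 (0.46 to 0.56, percentile 100). Fosb was higher by 0.745, Egr1 by 0.72 and Junb by 0.71. The median was 0.18 within cluster 2 and 0.26 within cluster 4, and the Atf3 ratio was 0.40 within cluster 2, which held 22.0% of sedentary and 37.1% of running cells. The same list differed little from the untreated library, with a median of 0.09 at percentile 58.1, and 7 of 24 measured members were higher than in both libraries and 0 lower (random lists 0.907 and 0.686). Heat shock genes had a median of 0.23 (0.08 to 0.31, percentile 99.9), with Hspa1a at 0.90, Dnajb1 at 0.67 and Hsp90aa1 at 0.66 but Hspb1 at -0.40. That median was 0.06 when every cell was thinned to 1000 UMIs and 0.025 (percentile 32.9) against the untreated library, and 2 of 14 were higher and 0 lower (0.798 and 0.686). Hspa1a was at 0.34 against the untreated library, Dnajb1 at -0.54 and Hsp90aa1 at -0.10. The ATF4 and amino acid response list had a median of 0.27 (-0.05 to 0.35, percentile 99.9), with Ddit3 at 0.59 and Cebpb at 0.51 but Herpud1 at -0.365. Against the untreated library it was 0.17 (percentile 67.2), and 3 of 15 were higher and 1 lower (1.33 and 0.933). Antigen presentation genes had a median of 0.18 (0.13 to 0.23, percentile 99.6) and 0.73 against the untreated library, with H2-Q7 at 0.88 and H2-Q4 at 0.48 but Tap2 at -0.28. Of 10 members 3 were higher and 0 lower (0.308 and 0.274), and these were the related genes H2-Q4, H2-Q6 and H2-Q7.

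Circadian clock genes were lower in the running than in both other libraries, with medians of -0.36 (-0.52 to -0.20, percentile 0.04) and -0.47 (percentile 0.03). Dbp, a clock output gene, had a ratio of -0.70 to the sedentary library, Tef of -0.51, Nr1d1 of -0.38 and Per3 of -0.38, and 6 of 14 measured members were lower than in both libraries and 0 higher (0.987 and 1.01 in random lists). Notch and arterial genes had a median of -0.18 (-0.25 to -0.08, percentile 0.44), with Notch4 at -0.58, Jag1 at -0.43 and Efnb2 at -0.40, and 2 of 16 were lower and 0 higher (0.594 and 0.65). That median was 0.03 when every cell was thinned to 1000 UMIs and -0.046 (-0.166 to 0.046) without the low-UMI cluster 5. Against the untreated library Notch4 was at 0.275, Jag1 at -0.546 and Efnb2 at -0.552. Interferon genes had a median of -0.12 (-0.18 to -0.04, percentile 1.0), with Ifit3 at -0.57 and Bst2 at -0.43 but Iigp1 at 0.67, and the median against the untreated library was 0.24. Ifit3 was at 0.34, Bst2 at 0.33 and Iigp1 at 1.20 against the untreated library. Of 28 measured members 2 were higher and 1 lower (0.784 and 0.808). Nuclear oxidative phosphorylation genes had a median of 0.06 (0.01 to 0.07, percentile 97.8), with Tfam at 0.43 and Uqcrc1 at -0.25, and 1 of 49 was higher and 0 lower (1.39 and 1.32). Without the low-UMI cluster 5 that median was -0.02.

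For running to sedentary, the other lists lay within the middle 95% of random lists. Against the untreated library some of these lay outside it, namely cell cycle (median 0.69), angiogenic (0.39), leukocyte adhesion (0.50), glycolysis (0.43), synthetase (0.43), TGF-beta (-0.17), flow response (-0.18, with a mean of 0.01 of the opposite sign) and glucocorticoid genes (-0.46). Leukocyte adhesion and inflammation genes had a median of 0.19 at percentile 97.48, the edge of that range, with Nfkbiz at 0.77, Cxcl1 at 0.76 and Relb at 0.56, and 6 of 16 were higher and 0 lower (1.71 and 1.19). To the untreated library, Nfkbiz was at 0.55 and Relb at 1.14 but Cxcl1 at -0.28. Cell cycle genes had a median of 0.09, with Ccnd1 at 0.47 and Tyms at 0.31, and 4 of 20 were higher and 2 lower (2.26 and 1.73). Angiogenic and tip cell genes had a median of 0.06, with Trp53i11 at 0.80 but Esm1 at -0.92 and Cxcr4 at -0.72, and 4 of 26 were higher and 1 lower (1.17 and 0.949). Basement membrane genes had a median of 0.03, with Nid2 at 0.60 and Lamb2 at -0.51, and 2 of 21 were higher and 0 lower (1.29 and 1.00). Amino acid transporters had a median of 0.02, with Slc1a5 at 0.56 and Slc43a3 at -0.36, and 2 of 6 were higher and 1 lower (0.183 and 0.178). Aminoacyl-tRNA synthetases had a median of -0.05, with Eprs at 0.47 and Yars at -0.29, and 0 of 13 were higher or lower (0.772 and 0.585).

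Glycolysis genes had a median of -0.002, with Ldha at 0.33 and Pfkl at -0.37, and 2 of 19 were higher and 0 lower (1.27 and 1.02). Hypoxia genes had a median of -0.02, with Adm at 0.59 and Epas1 at -0.54, and 2 of 16 were higher and 2 lower (0.86 and 0.764). TGF-beta and BMP genes had a median of -0.06, with Bmp6 at -0.68 and Ltbp4 at -0.67, and 1 of 19 was higher and 3 lower (0.81 and 0.738). Fatty acid genes had a median of -0.08, with Lpl, which encodes the lipase anchored by Gpihbp1, at -0.545, Dgat1 at 0.52, Acadl at -0.48 and Acsl1 at 0.47, and 2 of 24 were higher and 2 lower (1.29 and 0.965). Mitochondrial transcripts had a median of -0.08, with mt-Atp8 at -0.53, mt-Nd6 at 0.31 and mt-Nd4l at 0.175, and 0 of 13 were higher and 1 lower (0.48 and 0.418). Flow response genes had a median of -0.09, with Heg1 at -0.62 and Tek at -0.56 beside Edn1, and 1 of 18 was higher and 3 lower (0.811 and 0.639). Glucocorticoid response genes had a median of -0.11, with Sult1a1 at -0.59 but Errfi1 at 0.59 and Cdkn1a at 0.50, and 1 of 12 was higher and 2 lower (0.898 and 0.647). The mean log2 ratio was 0.03 for the synthetases, 0.03 for glycolysis and 0.01 for hypoxia, opposite in sign to the medians of these lists.

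**Figure D3:**
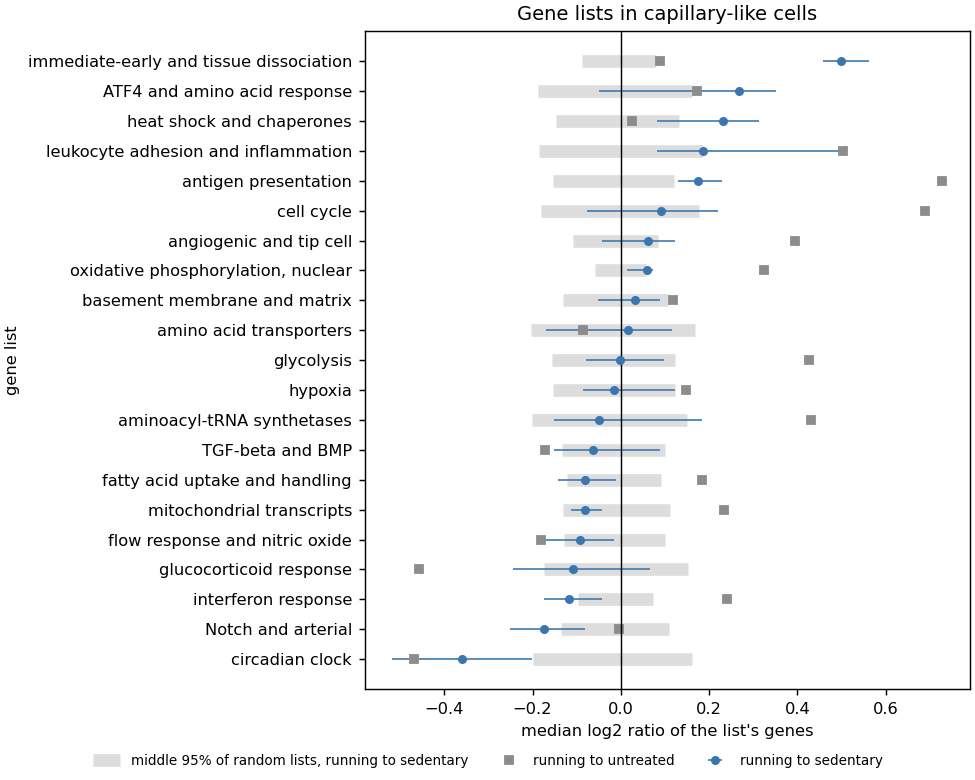
Median log2 ratio over the measured genes of each list in capillary-like cells (horizontal axis) by list (vertical axis), running to sedentary (circles, with lines for the 95% counting interval) and running to untreated (squares), over grey bars for the middle 95% of random lists for running to sedentary. The immediate-early list lay at 0.50 against the sedentary library and at 0.09 against the untreated library, and the circadian list at -0.36 and -0.47.

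In artery-like cells the running library had lower levels of the metallothionein gene Mt1, at 39.6 CPM against 148 in the sedentary library (log2 ratio -1.89, -2.43 to -1.41). Ybx3 (-1.02), Sox18 (-0.89) and Arrdc4 (-0.85) were also lower. Higher were the glutathione transferase gene Gstp1 (0.90), Pde12 (0.85), H2-Q7 (0.82), Htra1 (0.79) and Lgmn (0.75). In vein-like cells Ybx3 (-1.28), Igfbp3 (-1.12), Fam198b (-0.96) and Ski (-0.83) were lower, and the interferon-induced gene Iigp1 (0.94), the calcineurin regulator gene Rcan1 (0.93), Trp53i11 (0.83), H2-Q6 (0.82) and Csrp1 (0.81) were higher. H2-Q6 and H2-Q7 are near-identical, so their levels are uncertain.

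Between the untreated and sedentary libraries, capillary-like cells differed more than between the running and sedentary libraries. The untreated library had higher levels of the ubiquitin ligase gene Trim25, at 540 CPM against 114 (log2 ratio 2.24), of Net1 (2.06), of the TNF receptor gene Tnfrsf1b (2.03), of AC153143.1 (1.99) and of the netrin receptor gene Unc5b (1.93). It had lower levels of Erdr1 (-3.06), Fam221b (-2.84), Slx1b (-2.58), Amd2 (-2.34) and Ckap2 (-2.30). Over all genes the SD of log2 ratios was 0.628 for untreated to sedentary and 0.448 for running to sedentary. Haemoglobin and other erythrocyte markers were at 318 CPM in untreated, 1222 CPM in sedentary and 941 CPM in running capillary-like cells. The median of all genes was 0.12 for running to untreated, and TMM scaling moved it to 0.009, so ratios to the untreated library are relative to that shift. For running to sedentary it was -0.006.

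The share of capillary-like cells with an Atf3 UMI was higher in the running library. After thinning to 1000 UMIs it was 24.2% (382 of 1576 cells, 22.1 to 26.4) in the running, 16.7% (232 of 1390, 14.8 to 18.8) in the sedentary and 14.1% (277 of 1969, 12.6 to 15.7) in the untreated library. The difference between running and sedentary was 7.55 percentage points (4.60 to 10.5). Atf3 is on the immediate-early and tissue dissociation list, so handling of the sample stays open for this share too. Thinning left out 775 running, 1583 sedentary and 564 untreated cells, and without it the shares were 28.9%, 15.1% and 18.4%. In artery-like cells the thinned shares were 20.9%, 15.8% and 15.4%, leaving out 45, 137 and 160 cells, and 31.1%, 23.1% and 23.7% without thinning. In vein-like cells they were 28.8%, 18.6% and 33.8%, leaving out 21, 20 and 33 cells, and 46.1%, 35.8% and 52.1% without thinning, so the untreated library was the highest there. The capillary-like share with an Atf4 UMI was 28.2%, 23.3% and 23.5% after thinning and 35.7%, 24.2% and 32.2% without it.

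As background, 0 of 13 erythrocyte-like cells had an Atf3 UMI after thinning, which allows a share of up to 23.1%. Without thinning 4 of 14 (28.6%, 8.39 to 58.1) had one, 3 of 6 in the running and 1 of 8 in the sedentary library. Their median was 4623 UMIs before thinning, against 1258 in capillary-like cells, so these few cells set no useful limit on free RNA. Within the capillary-like class the share was 1.08% in untreated cells of cluster 3, and 4.06% and 4.84% in sedentary and running cells of cluster 4. It was 29.6% and 36.1% in sedentary and running cells of cluster 2, a cluster with early response genes among its leading genes. Atf3 lies on chromosome 1 from 191170296 to 191218039 and Atf4 on chromosome 15 from 80255184 to 80257541 (GRCm38).

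**Figure D4:**
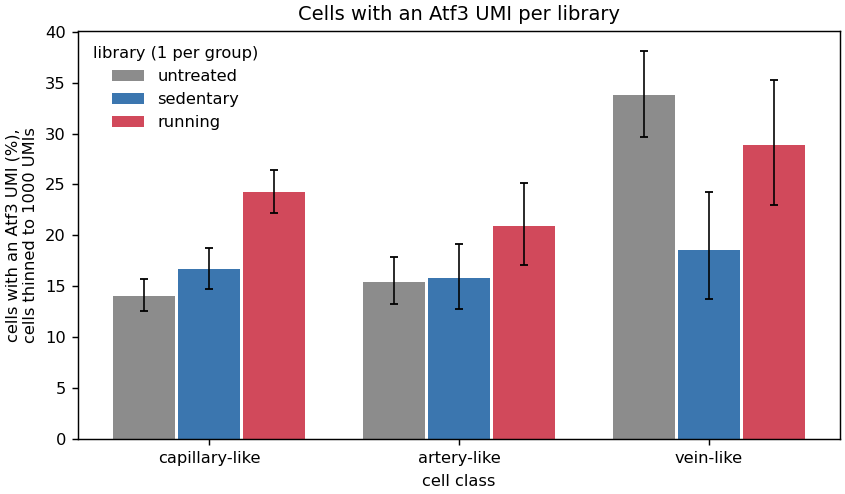
Share of cells with an Atf3 UMI (%, vertical axis) after thinning each cell to 1000 UMIs, by vessel class (horizontal axis) and library, with bars for the share and whiskers for the exact 95% binomial interval. In capillary-like cells the running library had 24.2% against 16.7% and 14.1%, and in vein-like cells the untreated library had 33.8% against 28.8% in the running library.

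Capillary-like cells with an Atf3 UMI were compared with those without. Of the cells with Atf3, 343 of 382 running and 201 of 232 sedentary cells were in cluster 2 and 256 of 277 untreated cells in cluster 0, so the contrast is also one between clusters. Higher with Atf3 were Fos (log2 fold change 0.89, SE 0.05), Jun (0.84, SE 0.05), the cytokine signalling inhibitor gene Socs3 (1.00, SE 0.08) and the flow-responsive factor genes Klf2 (0.71, SE 0.06) and Klf4 (0.87, SE 0.06), with adjusted p of at most 4.60e-28 by edgeR's quasi-likelihood test. Lower were the capillary genes Gpihbp1 (-0.51, SE 0.06, adjusted p = 2.90e-13) and Fabp4 (-0.45, SE 0.05, adjusted p = 1.22e-17) by the same edgeR test. Atf4 was also higher, at 0.60 (SE 0.10, edgeR adjusted p = 8.39e-07). These genes were singled out after their values were seen. Of 7726 genes tested, 158 were higher and 109 lower, with Benjamini-Hochberg adjustment at 0.05. Without the library block 0 and 0 passed by edgeR (391 at an unadjusted p under 0.05), DESeq2 gave 65 and 26, and thinning to 500 UMIs gave 75 and 19. Within cluster 2 alone, 0 were higher and 3 lower by edgeR among 4360 genes (169 at an unadjusted p under 0.05). Those 3 were the haemoglobin genes Hba-a1 (-1.11), Hba-a2 (-1.02) and Hbb-bs (-0.73), which erythrocytes express, and over all clusters their log2 fold changes were -0.76, -0.65 and -0.54. The log2 fold changes there were 0.14 (SE 0.08) for Fos, 0.12 (SE 0.10) for Socs3, -0.16 (SE 0.09) for Gpihbp1, -0.05 (SE 0.09) for Fabp4 and 0.31 (SE 0.13) for Atf4.

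By the rule for named genes, the genes with the largest fold changes were mostly of low counts. The exceptions among those higher were Apold1, an early response gene of endothelium (1.09, SE 0.09, edgeR adjusted p = 9.23e-28, 631 UMIs in cells with Atf3), Socs1 (1.22, SE 0.18, edgeR adjusted p = 8.00e-09, 123 UMIs) and the kinase gene Sik1 (1.40, SE 0.24, edgeR adjusted p = 1.67e-06, 69 UMIs). Log2 differences in the untreated, sedentary and running libraries were 1.022, 1.405 and 0.904 for Apold1. They were 0.407, 1.105 and 1.518 for Socs1 and 0.602, 1.561 and 1.729 for Sik1, a wider spread than their SE conveys. Coro7 (1.60), Noa1 (1.51), Cln3 (1.42), Axin1 (1.37), Pip4k2a (1.249), Gm11716 (1.18), Gm37125 (1.14), Gm43820 (1.14) and 3110082I17Rik (1.12) had 21 to 41 UMIs in cells with Atf3. Lower were Pstk (-2.43), Mcm7 (-1.90), Iars2 (-1.82), Hsd17b4 (-1.57), Eif2b2 (-1.49), Mpp1 (-1.30), Naxd (-1.21) and Mgst3 (-1.15), with 3 to 20 UMIs in cells with Atf3.

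Of the 22 measured immediate-early genes, 22 were higher in cells with Atf3 and 22 when adjusted over the list alone, with a median of 0.81. Atf3 belongs to this list and was left out here. The cells were thus split by a member of the list, so this is not an independent result about it. The list passed camera with the preset correlation (adjusted p = 1.62e-135) but not with an estimated one (adjusted p = 0.0923 with an estimated correlation, limma's camera). In the fatty acid list 5 of 21 were lower, Fabp4, Fabp5, Gpihbp1, Hadha and Mgll, and 7 when adjusted over the list alone, with camera adjusted p = 2.87e-07 and adjusted p = 0.265 with an estimated correlation. In the nuclear oxidative phosphorylation list 4 of 49 were lower, among them Uqcrc1 and Ndufa5, and 7 lower and 1 higher over the list alone (adjusted p = 9.06e-07 with camera, and adjusted p = 0.277 with an estimated correlation). Glucocorticoid response genes had 3 of 9 higher, Cdkn1a, Sgk1 and Klf9, and 1 lower, Sult1a1, with the same counts over the list alone (adjusted p = 1.21e-05 with camera, and adjusted p = 0.265 with an estimated correlation). Antigen presentation had 2 of 10 lower, B2m and H2-T23, and 4 lower and 1 higher over the list alone (adjusted p = 0.0017 with camera, and adjusted p = 0.265 with an estimated correlation). At the preset correlation camera also passed the amino acid transporter and leukocyte adhesion lists (adjusted p = 0.00369 each), the heat shock, Notch and TGF-beta lists (adjusted p = 0.00723 each), the angiogenic list (adjusted p = 0.00771) and the basement membrane list (adjusted p = 0.024). None of the 21 lists passed camera with an estimated correlation. In that form camera has only the 2 residual degrees of freedom of the fit, so passing over 21 lists was hardly possible. Not passing it therefore does not argue against a list.

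In the other lists, flow response genes had 2 of 16 higher, Klf2 and Klf4, and 3 lower, Aqp1, Cav1 and Cav2, and interferon genes 5 of 28 higher, among them Irf1, and 2 lower, Bst2 and Ifitm3. Over the list alone these were 4 and 3, and 6 and 3. The flow response list had a median of -0.13, opposite in sign to its mean of 0.01 and to the direction given by camera (adjusted p = 0.374). Leukocyte adhesion genes had 2 of 8 higher, Nfkbiz and Nfkbia, and Icam2 lower (3 and 1 over the list alone). Notch genes had 2 of 15 higher, Hes1 and Sox17 (3 higher and 1 lower), amino acid transporters 2 of 6, Slc38a2 and Slc6a6 (3 and 0), and heat shock genes 1 of 11, Dnajb1, with Hspb1 lower (6 and 1). The ATF4 list had 1 of 10 higher, Atf4 itself, the TGF-beta list 1 of 17, Id1, and the circadian list 1 of 10, Bhlhe40. Over the list alone 1, 2 and 1 were higher. Sparc was the 1 lower member of the angiogenic list of 24 and of the basement membrane list of 17, Mcm7 of the cell cycle list of 9 and Eno1 of the glycolysis list of 13. Adjusted over the list alone each of these again had 1 lower, and the angiogenic list also 1 higher. The synthetases (12 measured), mitochondrial transcripts (13) and hypoxia genes (14) had 0 past the threshold by edgeR, and hypoxia 1 lower over the list alone. Leaving out the sedentary library gave 92 higher and 54 lower genes, leaving out the running library 79 and 58, and a split by Atf4 gave 32 and 14.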

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

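The test of a clock shift shared by all vessel classes was chosen after its result was seen, and the alternative without cluster 5 after the data were seen.

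For 4 of the gene lists and named genes, the running to sedentary ratio had opposite signs in capillary-like cells and in another vessel class with both counting intervals excluding 0, and the difference itself was not tested. The median log2 ratio of nuclear oxidative phosphorylation genes was -0.117 in vein-like and 0.06 in capillary-like cells. That of mitochondrial transcripts was 0.132 in artery-like and -0.081 in capillary-like cells. Without cluster 5 the capillary-like medians were -0.024 (-0.057 to 0.003) and -0.033 (-0.051 to 0.027), so neither interval excluded 0, and with cells thinned to 1000 UMIs they were -0.026 and 0.041. Ccnd1, which encodes a cyclin, had a log2 ratio of -0.555 in vein-like and 0.47 in capillary-like cells. Dbp, a clock output gene, had 0.448 in artery-like and -0.704 in capillary-like cells.

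Circadian genes as a list were lower in running than in sedentary capillary-like cells. Between these libraries, the artery-like median was 0.116 (-0.158 to 0.357), above the capillary-like interval of -0.518 to -0.202. The vein-like median was -0.384, and the artery-like median against the untreated library was -0.302 (-0.625 to 0.027). A shift of the clock shared by all vessel classes stays open, since these values differ in direction and that test was chosen after its result was seen. A different clock phase when tissue was taken also stays open, and with 1 library per group it cannot be told apart from running. The test of a different phase could not decide. The mean log2 ratio of Arntl and Clock, which peak opposite to Dbp, was -0.091 (-0.35 to 0.165), and Npas2 had too few UMIs. A larger number of low-UMI cells in the sedentary library may contribute, since the median without cluster 5 was -0.284 and its interval, -0.548 to -0.145, reached past the bound of -0.15 set for that test. An effect of running also stays open, and with 1 library per group it was not tested.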

How the results depend on the processing

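Alternatives leaving out cluster 5, using cluster 2 or 4 alone, or leaving out the highest 5% of doublet scores were chosen after seeing the data. The cause was not tested where a value moved or changed sign. The circadian median kept its direction under the 18 alternatives tried (-0.478 to -0.204), the lymphatic-like share difference under 6 (1.116 to 1.166 points) and the ATF4 list median under 18 (0.128 to 0.274). Of 408 values for 24 other genes, 379 stayed within the counting interval and 408 kept their direction. Of 234 values for the 13 other lists, 200 stayed within it and 182 kept their direction. The 24 genes were chosen for large ratios of the same sign against the untreated library, itself an alternative. Their kept directions were thus partly built in. Sizes moved more, for example from 0.313 to 3.104 for Egr2, 0.381 to 2.126 for Arc and -0.995 to -0.233 for Trappc8. No cluster was named lymphatic-like at a minimum of 500 genes, nor in the sedentary library when each was clustered alone, so these say nothing about that direction. Depth limits the capillary-like comparisons, at a sedentary median of 930 UMIs per cell.

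Medians below are log2 ratios and shares are percentage points, running against sedentary. With a minimum of 500 genes per cell, the immediate-early median was 0.451, Notch -0.036, interferon -0.183 and oxidative phosphorylation -0.011. The capillary-like, artery-like and vein-like share differences were then 5.332, -4.729 and -0.603. With a mitochondrial maximum of 5% they were -3.476 for capillary-like and -0.182 for artery-like cells. The artery-like difference was -0.219 at Leiden resolution 0.5 and -0.426 without the highest doublet scores. Clustered without stress and amino acid genes, the capillary-like difference was -3.449 and the artery-like 0.836. With each library clustered alone they were -7.925 and 6.061, the immediate-early median was 0.617 and the Atf3 ratio 1.026.

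With every cell thinned to 1000 UMIs, the medians were 0.388 for immediate-early, 0.057 for heat shock, 0.027 for Notch and -0.026 for oxidative phosphorylation genes, and the Atf3 ratio was 0.667. With means of per-cell shares, immediate-early, Notch and oxidative phosphorylation medians were 0.643, -0.269 and 0.102. Over all endothelial-like cells the immediate-early median was 0.383 and the Atf3 ratio 0.700. Without cluster 5, immediate-early, Notch and oxidative phosphorylation medians were 0.394, -0.046 and -0.024, and the Atf3 ratio was 0.701. In cluster 2 alone the immediate-early, Notch and antigen presentation medians were 0.179, -0.051 and 0.283, and the Atf3 and Atf4 ratios 0.402 and 0.111. In cluster 4 alone the immediate-early and antigen presentation medians were 0.259 and 0.248, and the Atf3 ratio 0.621. Against the untreated library the medians were 0.088 for immediate-early, 0.025 for heat shock, 0.325 for oxidative phosphorylation, -0.003 for Notch, 0.24 for interferon and 0.728 for antigen presentation genes.

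The difference in the share of cells with an Atf3 UMI was 13.8 points without thinning and otherwise 4.927 to 9.331, the lowest being for Atf4 in place of Atf3. In the contrast of cells with and without an Atf3 UMI, cluster 2 alone gave 0 genes higher and 3 lower by edgeR, with 169 at an unadjusted p under 0.05 and fewer cells and genes tested. Removing the library block, which pairs the sums of each library, left 0 genes higher and 0 lower by edgeR, with 391 at an unadjusted p under 0.05. With the block, DESeq2 found 65 higher and 26 lower among 1136 genes with an adjusted p. No low-count filter gave 78 higher (and 129 lower), a split by Atf4 32 and 14, and thinning to 500 UMIs 75 and 19. Leaving out each library in turn gave 79 to 146 higher and 54 to 92 lower, with the lowest counts of 79 without the running and 54 without the sedentary library.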

Other observations

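The test that leaves out cluster 5 uses an alternative chosen after the data were seen.

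The antigen presentation list had a median running to sedentary log2 ratio of 0.19 (0.14 to 0.29, percentile 99.6) in artery-like and 0.23 (0.13 to 0.36, percentile 99.1) in vein-like cells. Of its members, 2 of 10 in artery-like and 5 of 11 in vein-like cells were higher than in both other libraries (0.214 and 0.61 in random lists), and 0 and 1 were lower (0.272 and 0.52). Interferon genes had medians of -0.13 in artery-like and 0.16 in vein-like cells. Circadian genes had a median of -0.38 (-0.66 to 0.02) in vein-like cells. Atf3 was at 325, 280 and 276 CPM in running, sedentary and untreated artery-like cells, and at 525, 371 and 605 CPM in vein-like cells.

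Immediate-early genes were higher in running than in sedentary capillary-like cells. A larger number of low-UMI cells in the sedentary library is argued against as the whole cause, since the median without cluster 5 was 0.394 (0.348 to 0.445) and the bound set for that explanation was 0.2. Handling of the whole sample during dissociation stays open, since the list was also higher in the other classes, at 0.207 (0.021 to 0.215) in artery-like and 0.317 in vein-like cells. Against the untreated library these medians were -0.29 and -0.39, so the running library was not the highest in those classes. Against the sedentary library, an effect of running on all vessel classes would also give higher medians in each class. With 1 library per group that effect was not tested.

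Ccl21a, a gene of lymphatic endothelium, was higher in running than in sedentary capillary-like cells. Free RNA from lymphatic-like cells may account for this, since the log2 ratio was 2.507 (1.91 to 3.207) in artery-like and vein-like cells together and the running level was 85.1, 75.3 and 86.3 CPM in capillary-like, artery-like and vein-like cells. The number of lymphatic-like cells alone does not order the libraries, since the running, sedentary and untreated libraries had 44, 10 and 27 of them and the untreated capillary-like level was 3.5 CPM. In lymphatic-like cells the level was 30150 CPM in the running, 24954 CPM in the sedentary and 19757 CPM in the untreated library, the order of the capillary-like levels, which were 85.1, 11.6 and 3.5 CPM. The levels in lymphatic-like cells lay far closer together than the capillary-like levels. Summed over lymphatic-like cells there were 4019 running, 517 sedentary and 1570 untreated Ccl21a UMIs, which is not the order of the capillary-like levels. An effect of running on Ccl21a in capillary-like, artery-like and vein-like cells was not tested and stays open.

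Of the 10 splits of the 6 sums into 3 and 3, only the division by Atf3 itself (1 split) reached its 267 genes past the threshold, and the highest other value was 0. Of these splits, 4 part the sums of each library, and the other 3 of them gave 0. With 10 splits a share under 0.05 cannot be reached.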
